A study of Drosophila melanogaster with 4 samples.

How the data were processed

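RNA was sequenced from pooled central nervous systems of Drosophila melanogaster larvae, in 2 control and 2 reprogrammed samples of 70 to 100 nervous systems each, at 96 hours after egg laying. Per the labels' protocols, messenger RNA was selected with oligo(dT) beads, fragmented and copied into DNA from random primers, and the libraries were made into single-stranded circles. The protocol names no step that marks strand, so antisense and overlapping genes cannot be told apart here. The authors deposited 1 table per sample with FPKM values per gene, rounded to 2 decimals, per the file headers. Bowtie2 and HISAT are named in the submitters' processing notes. Their versions, the quantifier and the genome build are not given in the sources used here, so no coordinates are printed. FPKM divides by transcript length and by the mapped total, so a few abundant genes can shift all others, and a difference in RNA integrity between libraries can change values with transcript length.

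The tables name genes by NCBI gene number and RefSeq transcript. Over the 4 libraries 13997 genes were listed, 10945 of them in all libraries, and a gene missing from a library's table was set to 0. A RefSeq gene table of assembly Release 6 plus ISO1 MT was used for names only: 13960 genes were named by gene number, 1 by transcript accession, and 36 had no name. Transcript lengths, the longest annotated transcript per gene, came from an Ensembl BDGP6 annotation and were found for 9839 of the 9851 tested genes. The worth of 1 read was estimated from the steps between low FPKM values of single-transcript genes longer than 600 bases. With a tolerance of 0.15 reads, between 93.2% and 95.3% of those values came out whole, against 30.0% by chance. This gives depth, but FPKM values do not give counts for all genes, so no count-based test was run.

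Groups were taken from the sample titles. Genes at 1 FPKM or more in at least 2 of the 4 libraries were tested on log2(FPKM + 1) with limma (lmFit, then eBayes with a mean-variance trend), with group as the only term, two-sided, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The fit had 2 residual and 3.72 prior degrees of freedom. Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, adjusted over the 36 lists, and again with an estimated correlation, under which none of the lists passed. They hold glial markers, neural stem cell genes, their early and late temporal genes, ganglion mother cell and newborn neuron genes, mature neuron genes, optic lobe progenitor genes, neuropeptides, axon guidance, G1/S and mitosis genes, ribosome biogenesis genes and ribosomal proteins. The others hold Egfr and Ras/MAPK, insulin and PI3K, JNK and invasion, JAK/STAT, Notch, Wnt, Hippo, ecdysone, chromatin, glycolysis, mitochondrial respiration, lipid, immunity, stress and apoptosis genes, markers of blood cells, fat body, muscle, imaginal discs, salivary and ring glands, trachea and cuticle, and gut, and general control genes. Of the names written, 973 matched a symbol, 38 a synonym and 14 nothing.

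Genes named were Egfr, Pi3K92E and repo, then the 10 largest increases and the 10 largest decreases among called genes whose libraries did not overlap between groups and whose higher group averaged at least 5 FPKM, then up to 4 called members of each list and up to 2 uncalled members of highest FPKM in lists that were mixed or not changed. Genes named outside this rule are said to be so. Each gene's mean ± SD is over 2 libraries. Alternatives set before the data were examined were scaling to a common median, no filter, a filter of 5 FPKM, a pseudocount of 0.1, a log2 change of at least 1, the replicate number as a block, each library left out in turn, and the estimated correlation. Scaling to a common sum, quantile normalization, removal of the trend on transcript length (loess, span 0.5) and counting genes with identical values once were chosen after seeing the data. With 1 library left out, the lone library of its group is assumed to vary like the pair of the other.

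The gene test was checked on simulated values for the comparison of 2 reprogrammed with 2 control libraries over 9851 genes, 200 of them changed. It recovered 4.5% of genes changed 2-fold, 38.8% of those changed 4-fold and 95.5% of those changed 8-fold, with 2 false calls among 95. The simulated genes shared 1 common level of spread, and the changed ones lay above 5 FPKM. In the data the spread differs between genes and groups, so these rates need not hold there. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.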

Results

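The central nervous systems of Drosophila melanogaster larvae were profiled by RNA sequencing at 96 hours after egg laying. In the 2 control samples the glial driver repo-Gal4 expressed the red fluorescent protein mRFP. In the 2 reprogrammed samples, named so in the labels, the same driver expressed activated forms of Egfr, the receptor for epidermal growth factor ligands, and PI3K92E, the catalytic subunit of phosphoinositide 3-kinase. Gal4 is a yeast transcription factor that switches on genes placed behind its binding sites, so the products were directed to glia, the support cells of the nervous system. Each sample pooled 70 to 100 dissected nervous systems. The values are FPKM, fragments per kilobase of transcript scaled to the mapped total. The steps between low values put 1 FPKM over 1 kilobase at 11.6 and 12.2 reads in control replicates 1 and 2, and at 11.2 and 11.5 reads in reprogrammed replicates 1 and 2. Between 12192 and 12620 genes were listed per library, and 9851 genes reached 1 FPKM in at least 2 libraries and were tested. Fold changes below are reprogrammed minus control on the log2(FPKM + 1) scale, which understates the change of low genes, with standard errors and Benjamini-Hochberg adjusted p from limma, two-sided, n = 2 per group. The p-values measure the spread between these pooled samples, which may be technical.

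The comparison asked how the nervous system's transcript levels differed when both activated proteins were expressed in glia. The groups differ in genotype, so any other difference between the fly lines cannot be told apart from expression of these proteins. Egfr (NCBI gene 37455) stood at 8.60 and 11.4 FPKM in control and at 58.9 and 49.3 in reprogrammed samples, an increase of 2.33 ± 0.30 (SE; limma adjusted p = 0.0299). Pi3K92E (NCBI gene 42446) rose from 12.7 ± 6.24 to 270.0 ± 24.7 FPKM (SD, n = 2), by 4.38 ± 0.38 (limma adjusted p = 0.0206). The glial transcription factor repo (NCBI gene 47285), whose regulatory sequence drives Gal4, rose from 18.1 ± 8.01 to 56.1 ± 6.51 FPKM, by 1.64 ± 0.38 (limma adjusted p = 0.0474). For Egfr and Pi3K92E the files do not separate transcripts of the transgenes from those of the endogenous genes. The call for repo was lost on a common sum of FPKM (adjusted p = 0.0735), with a pseudocount of 0.1 (0.0520) and without reprogrammed replicate 1 (0.332) or 2 (0.133). Egfr lost its call without reprogrammed replicate 1 (adjusted p = 0.104). With no filter on low values none of these 3 genes passed in limma (Egfr 0.0843, Pi3K92E 0.0843, repo 0.0971).

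Across the transcriptome, 405 genes were higher and 801 lower in reprogrammed samples, so 33.6% of the calls were higher. With no filter on low values limma called 0 genes higher and 0 lower of 13997, with 3629 at an unadjusted p under 0.05 and a smallest adjusted p of 0.084. The called genes changed by at least 1.09 on the log2 scale, with a median of 2.15 among higher and −1.70 among lower genes. The median change of all tested genes was −0.25. It was −0.06 with libraries scaled to a common median, −0.50 on a common sum of FPKM and −0.04 after quantile normalization. The higher share of the calls moved with the scaling, to 46.0% on a common median, 20.3% on a common sum, 59.7% after quantile normalization and 46.9% with a trend on transcript length removed. No gene among the 1206 main calls changed sign in any of these fits. The calls all had changes of at least 1.09, so a kept sign says little about stability. The control libraries differed from each other more than the reprogrammed libraries did, with an SD of the log2 difference of 0.88 against 0.59. Without control replicate 1, 1265 genes were higher and 3313 lower. Without control replicate 2 the numbers were 1221 and 1645. Without reprogrammed replicate 1 they were 181 and 75, and without reprogrammed replicate 2 they were 279 and 201. Without a reprogrammed library the spread came from the control pair alone, with 1 residual degree of freedom and infinite prior degrees of freedom. Calls lost in those fits, here and below, can reflect this variance estimate and do not by themselves show dependence on 1 reprogrammed library. Without a control library the spread came from the closer reprogrammed pair alone. The larger numbers of calls in those fits, here and below, can likewise reflect the variance estimate. Among the 118 called genes named in this text, none changed sign with any library left out. They were called for changes large against the spread between libraries, so this was nearly fixed in advance.

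The 10 largest increases among genes at 5 FPKM or more included GstD2, a glutathione S-transferase of detoxification, and a copy of the histone gene His2A. GstD2 rose from 1.48 ± 0.39 to 92.2 ± 0.99 FPKM, by 5.24 ± 0.30 (limma adjusted p = 0.0143). His2A:CG33808 was missing from the tables of both controls, where it was set to 0, and stood at 29.6 and 62.8 FPKM in the reprogrammed libraries, and its reads can be shared with near-identical copies. For such histone copies, values after oligo(dT) selection may not stand for total transcripts. CG6357 reached the highest level of the 10, with 6796 ± 2381 FPKM against 169.1 ± 68.5 in controls, a rise of 5.34 ± 0.46 (limma adjusted p = 0.0206). CG11893 rose from 2.04 ± 1.46 to 269.3 ± 61.9 FPKM and CG33468 from 0.22 ± 0.11 to 76.4 ± 21.2, both at a limma adjusted p of 0.0143. The long noncoding RNA lncRNA:CR44138 rose by 6.46 ± 0.76, with 521 and 116 FPKM in the reprogrammed libraries. The remaining 4, CG6908, CG17224, CG14949 and CG14933, rose by 5.35, 4.78, 4.71 and 4.69.

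The largest decreases included ImpE2, an ecdysone-inducible gene of imaginal discs, and Fbp1, which encodes a fat body receptor for larval serum protein. ImpE2 fell from 333 ± 179 to 15.3 ± 4.87 FPKM, by 4.28 on the log2 scale with an SE of 0.46 (limma adjusted p = 0.0297). Fbp1 stood at 33.7 ± 16.0 FPKM in control and 1.83 ± 2.43 in reprogrammed samples (log2 change −3.87 ± 0.73, limma adjusted p = 0.0384), a call lost with a pseudocount of 0.1 (0.0607) and after quantile normalization (0.0624). CG9021 showed the largest decrease, from 118.2 ± 66.3 to 0.38 ± 0.10 FPKM (−6.31 ± 0.47, limma adjusted p = 0.0189). CG34296 followed, from 1128 ± 204 to 29.9 ± 9.33 FPKM (−5.21 ± 0.33). Ada1-1, which encodes a subunit of histone acetyltransferase complexes, read 22.9 and 15.5 FPKM in the controls and was missing from the tables of both reprogrammed libraries. The serpin genes Spn100A and Spn43Aa, whose family inhibits serine proteases, changed by −3.54 and −3.35. Jhbp2, a predicted juvenile hormone binding protein, changed by −3.53, CG42822 by −3.56 and CG12828 by −2.93.

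Glial genes were higher as a set with the preset correlation, though most single markers did not pass. Of 42 measured markers, 12 rose, 1 fell and 29 did not pass the test over all genes. With the adjustment over the list alone, 22 were higher and 3 lower. The list median was 0.95 (camera adjusted p = 6.91e-07 with the preset correlation, adjusted p = 0.61 with an estimated correlation). The steepest rises were those of the blood-brain barrier genes moody, a G protein-coupled receptor, from 20.1 ± 5.63 to 212 ± 7.72 FPKM (3.36 ± 0.30, limma adjusted p = 0.0209), and Mdr65, a drug efflux transporter, from 24.2 ± 12.9 to 211 ± 38.5 (3.16 ± 0.42, limma adjusted p = 0.0315). Ntan1 rose by 2.61 ± 0.30. The glial fate switch gcm went the other way, from 8.01 ± 0.75 to 0.64 ± 0.04 FPKM (−2.46 ± 0.31, limma adjusted p = 0.0297; 0.0512 without reprogrammed replicate 1). The 2 most abundant markers without a call were the adhesion gene Lac, at 244 ± 49.3 and 489 ± 51.7 FPKM, and the gap junction gene Inx2, at 302 ± 59.8 and 252 ± 26.0. The list median was 0.41 higher in control replicate 2 than in control replicate 1. Of the 42 genes, 6 also stand in another list. On all 4 libraries 31 of the 42 changes were positive and 11 negative, called or not. With 1 library left out the list median ranged from 0.85 to 1.11.

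**Figure D1:**
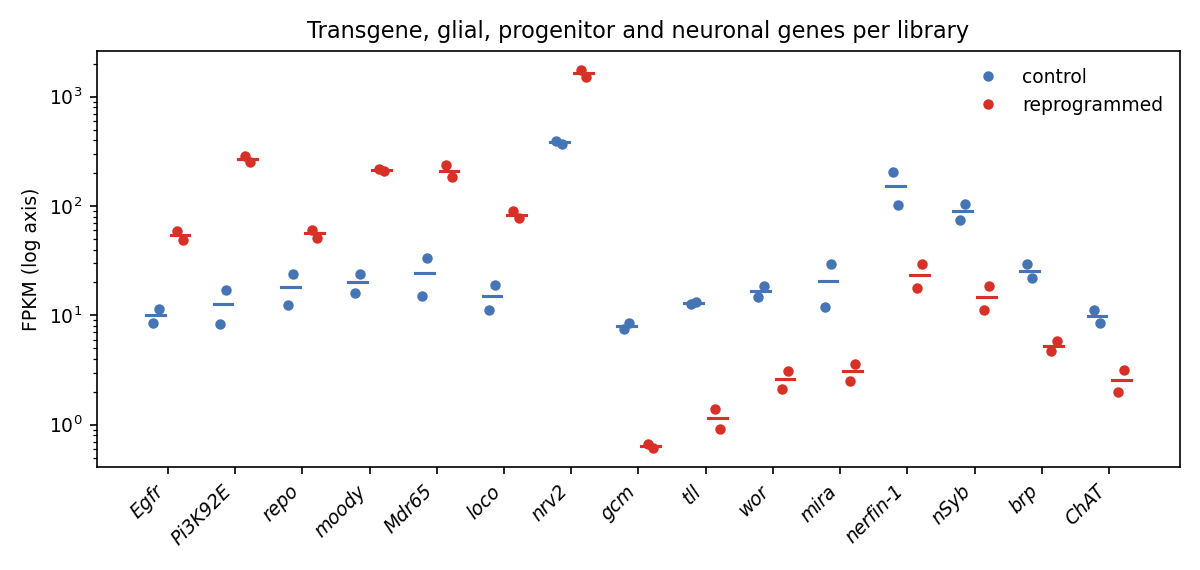
FPKM on a log axis of 15 transgene, driver, glial, progenitor and neuronal genes in each of the 4 libraries, with control libraries in blue, reprogrammed libraries in red, points for single libraries and horizontal lines for the mean of each group (n = 2). The points of Pi3K92E lie at 8.28 and 17.1 in control and 287 and 253 in reprogrammed samples, and those of nSyb at 74.1 and 104.6 against 11.2 and 18.4.

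Lists of genes of neurons and of their progenitors were lower as sets with the preset correlation. Among mature neuron genes, 28 of 45 fell, none rose and 17 did not pass. Adjusted over the list alone, 42 were lower. Over all genes, 19 were lower on a common median, 35 on a common sum and 10 after quantile normalization. The list median was −1.65 (camera adjusted p = 3.8e-12, adjusted p = 0.61 with an estimated correlation). The synaptic vesicle gene nSyb changed from 89.3 ± 21.6 to 14.8 ± 5.11 FPKM (−2.53 ± 0.36, limma adjusted p = 0.0324). Appl, the fly amyloid precursor protein, fell by 2.41 on the log2 scale (SE 0.29), and the cytoskeletal adaptor Ank2 by −2.08 ± 0.38. Neural stem cell genes had a median of −1.65 as well (camera adjusted p = 1.31e-06, adjusted p = 0.61 with an estimated correlation), with 16 of 34 lower and none higher. Adjusted over the list alone, 26 were lower and 1 higher. Transcription factors led this list: tll by −2.71 ± 0.33, esg and erm both by −2.35, and sna by −2.31. Of 15 genes of ganglion mother cells, the dividing daughters of stem cells, and of newborn neurons, 10 fell (12 adjusted over the list alone; median −1.80; camera adjusted p = 5.85e-05, adjusted p = 0.61 with an estimated correlation). They included nerfin-1 (−2.60 ± 0.44), the RNA-binding gene fne (−2.33 ± 0.34), tap (−2.26 ± 0.38) and the fate determinant pros (−2.05 ± 0.35). The lower genes of these 2 lists numbered 26 and 12 without control replicate 1, 24 and 12 without control replicate 2, 1 and 1 without reprogrammed replicate 1, and 9 and 5 without reprogrammed replicate 2. Without reprogrammed replicate 1 the calls of esg, erm, sna, fne, tap, pros and Ank2 were lost (adjusted p from 0.0581 for fne to 0.209 for tap), and without reprogrammed replicate 2 that of esg (0.0511). With the length trend removed pros (limma adjusted p = 0.0803) and Ank2 (0.114) lost theirs. On a common median pros (0.0542) and Ank2 (0.051) did, and after quantile normalization tap (0.0507) and Ank2 (0.0566).

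The decrease reached further neural groups. Among 20 optic lobe progenitor genes 8 fell, or 16 adjusted over the list alone with 1 higher (median −1.48, camera adjusted p = 3.94e-05, adjusted p = 0.61 with an estimated correlation). Among 37 neuropeptide and peptide-processing genes 12 fell, or 20 adjusted over the list alone (median −1.41, camera adjusted p = 8.92e-06, adjusted p = 0.66 with an estimated correlation), led by Hug (−2.52), Dh44 (−2.31), AstC (−2.07) and the prohormone convertase amon (−1.93). Axon guidance and adhesion genes had 12 lower and 1 higher of 38, Fas1, chosen after its value was seen, and 26 lower and 1 higher adjusted over the list alone (median −1.16, camera adjusted p = 6.63e-06, adjusted p = 0.61 with an estimated correlation). The lower ones numbered 21 on a common sum, 6 on a common median, 2 after quantile normalization and 1 with the length trend removed. Among the axon guidance genes, trn, robo3 and Dscam2 changed by −2.39, −2.11 and −2.15. Dscam2 lost its call on a common median (limma adjusted p = 0.0735), after quantile normalization (0.0967) and with the length trend removed (0.101). The robo3 call was lost after quantile normalization (0.0566) and with that trend removed (0.0548). After quantile normalization AstC (0.0554) and Fas1 (0.0681) lost theirs, and Fas1 also on a common sum (0.0509). Of the 5 early temporal genes of neural stem cells, chinmo and dati fell (4 adjusted over the list alone; median −1.23; camera adjusted p = 0.112, 0.74 with an estimated correlation). Both lost their calls with the length trend removed (chinmo −0.32, adjusted p = 0.538; dati 0.0504) and without reprogrammed replicate 1 (0.469 and 0.205) or 2 (0.301 and 0.0650), and chinmo also on a common median (0.0564) and after quantile normalization (0.0562). Of the 5 late temporal genes mamo fell (3 adjusted over the list alone; median −1.36; camera adjusted p = 0.0399, adjusted p = 0.68 with an estimated correlation). Without control replicate 1 the lower optic lobe, neuropeptide and axon guidance genes numbered 15, 25 and 25, and without control replicate 2 they numbered 13, 14 and 23. Without reprogrammed replicate 2 limma gave 4, 6 and 2, and without reprogrammed replicate 1 it gave 1, 1 and 0 (10, 9 and 9 at an unadjusted p under 0.05). The calls of Dh44, AstC, amon, trn, robo3, Dscam2 and Fas1 were lost without reprogrammed replicate 1 (adjusted p from 0.0837 for trn to 0.428 for Fas1), those of amon (0.0812), robo3 (0.0521) and Fas1 (0.154) without reprogrammed replicate 2, and that of AstC without control replicate 2 (0.0563). The mamo call was lost on a common median (0.0518), after quantile normalization (0.0650), with the length trend removed (0.135) and without reprogrammed replicate 1 (0.279) or 2.

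Long transcripts were lower in the reprogrammed libraries as a whole. The median change was 0.20 in the eighth of genes with the shortest transcripts and −0.96 in the eighth with the longest. Mature neuron genes had a median change of −0.87 and neural stem cell genes of −1.33 once that trend was removed, and both lists kept their call (camera adjusted p = 8.46e-06 and 0.000163). Single calls became fewer, with 4 mature neuron, 9 neural stem cell and 6 ganglion mother cell and newborn neuron genes lower. Axon guidance genes lost the list call (median −0.49, camera adjusted p = 0.141), as did the late temporal genes (median −0.52, camera adjusted p = 0.710). The late temporal call was also lost on a common median (0.0765), with the replicate block (0.0501), without control replicate 1 (0.193) and without reprogrammed replicate 2 (0.0813). The number of mature neuron genes called lower was 2 without reprogrammed replicate 1, 9 without reprogrammed replicate 2, 42 without control replicate 1 and 36 without control replicate 2.

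**Figure D2:**
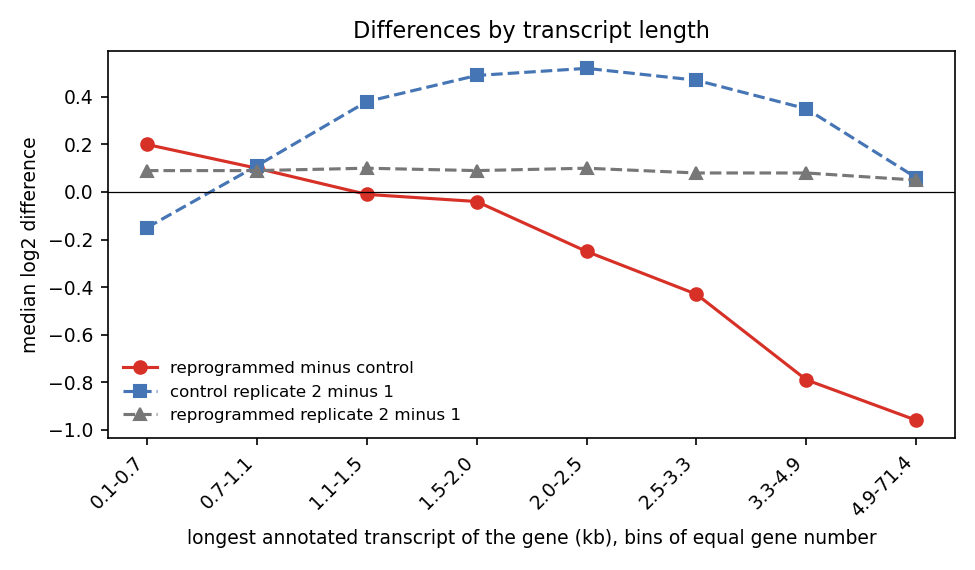
Median log2 difference of tested genes against the length of the longest annotated transcript, in 8 bins of equal gene number, for reprogrammed minus control (red), control replicate 2 minus 1 (blue) and reprogrammed replicate 2 minus 1 (grey). The red line goes from 0.20 in the shortest bin to −0.96 in the longest, while the grey line stays between 0.05 and 0.10. The blue line goes from −0.15 in the shortest bin up to 0.52 and back to 0.06 in the longest, so the 2 controls also differ with transcript length.

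Most genes of the Egfr and PI3K pathways did not pass the test on all 4 libraries. These lists mix signalling components with target and feedback genes, so their medians and camera results do not measure pathway activity, which was not tested. Among 25 Egfr and Ras/MAPK pathway genes, Mkp3, a phosphatase that limits MAP kinase signalling, rose from 21.7 ± 0.49 to 72.7 ± 10.5 FPKM (1.69 ± 0.27, limma adjusted p = 0.0336), phyl and mirr fell (−2.26 and −1.41), and 22 did not pass. Adjusted over the list alone, 2 were higher and 4 lower (median −0.39, camera adjusted p = 0.88, 0.94 with an estimated correlation). The ligand gene spi stood at 387 ± 75.3 and 476 ± 43.7 FPKM, and the MAP kinase gene rl at 292 ± 135 and 286 ± 23.8. Among 25 insulin, PI3K, Tor and Foxo genes, ImpL2, an insulin-binding secreted protein, rose from 79.7 ± 1.53 to 297 ± 32.1 FPKM (1.88 ± 0.26, limma adjusted p = 0.0324) and the lipase gene Lip4 by 1.28 ± 0.29. The other 23 did not pass, among them Thor, the fly 4E-BP, at 159 ± 30.6 and 113 ± 58.7 FPKM, and Akt at 80.2 ± 16.6 and 62.1 ± 0.17. Adjusted over the list alone 1 was higher (median −0.58, camera adjusted p = 0.557, 0.87 with an estimated correlation). Lip4 lost its call on a common sum (limma adjusted p = 0.0701), after quantile normalization (0.0612) and with the length trend removed (0.066). The mirr call was lost with a pseudocount of 0.1 (0.0538), after quantile normalization (0.0883) and with that trend removed (0.106). Without control replicate 1, 4 Egfr pathway genes were higher and 8 lower, and 3 insulin and PI3K genes were higher and 12 lower. Without control replicate 2 these numbers were 2 and 7, and 4 and 5. In limma they were 0 and 0 for both lists without reprogrammed replicate 1 (1 and 1, and 1 and 0, at an unadjusted p under 0.05), and 1 and 1, and 1 and 0, without reprogrammed replicate 2. Mkp3, phyl, mirr, ImpL2 and Lip4 lost their calls without reprogrammed replicate 1 (adjusted p = 0.302, 0.253, 0.401, 0.167 and 0.531), and Mkp3, mirr and Lip4 without reprogrammed replicate 2 (0.0977, 0.388 and 0.183).

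Lists of Notch, Wnt, Hippo and ecdysone genes were lower as sets with the preset correlation, while most of their genes did not pass over all genes. Of 24 Notch pathway and E(spl) complex genes 7 fell, or 16 adjusted over the list alone (median −1.32, camera adjusted p = 5.37e-05, adjusted p = 0.62 with an estimated correlation), with E(spl)m5-HLH at −2.57 ± 0.42 and E(spl)malpha-BFM at −2.33 ± 0.41. Of 20 Wnt pathway genes 4 fell, or 13 adjusted over the list alone (median −1.06, camera adjusted p = 5.96e-05, adjusted p = 0.61 with an estimated correlation): the feedback inhibitor nkd (−2.08), the ligands wg (−1.93) and Wnt4 (−1.74), and Apc (−1.49). Of 20 Hippo pathway genes the growth regulators fj, ds, crb and ft fell, or 6 adjusted over the list alone (median −0.73, camera adjusted p = 0.0399, adjusted p = 0.72 with an estimated correlation). Of 20 genes of the ecdysone response 5 fell and 1 rose, ImpE1, chosen after its value was seen, or 10 and 2 adjusted over the list alone (median −1.07, camera adjusted p = 0.0120, adjusted p = 0.61 with an estimated correlation). Nuclear receptor genes were among the lower ones, with Hr3 at −2.06, Eip78C at −1.97 and Hr4 at −1.90. The labels used here give hours after egg laying only, so a difference in developmental stage between the groups was not tested. The Hippo and ecdysone lists lost their calls with the length trend removed (camera adjusted p = 0.765 and 0.360), and the Hippo list also at 5 FPKM or more (0.0707), with the replicate block (0.0811) and without control replicate 2 (0.102) or reprogrammed replicate 2 (0.155). The lower Notch, Wnt, Hippo and ecdysone genes numbered 18, 15, 13 and 12 without control replicate 1 and 14, 12, 6 and 10 without control replicate 2. In limma they numbered 0, 0, 0 and 2 without reprogrammed replicate 1 (7, 3, 3 and 7 at an unadjusted p under 0.05) and 3, 0, 0 and 1 without reprogrammed replicate 2 (13, 4, 4 and 7). All 14 genes named here lost their calls without reprogrammed replicate 1 (adjusted p from 0.0826 for E(spl)malpha-BFM to 0.478 for Apc), and the 12 outside the E(spl) complex also without reprogrammed replicate 2 (from 0.0585 for ImpE1 to 0.309 for crb). With the length trend removed 9 of the 14 lost theirs, from 0.0510 for Wnt4 to 0.498 for ft.

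The JNK and invasion list rose as a set, with the secreted genes SPARC (2.71 ± 0.46), ImpL2 and Pvf2 (1.41 ± 0.31) higher of 27, the kinase gene wnd lower (−1.71 ± 0.34) and 23 not passing. Adjusted over the list alone, 7 were higher and 3 lower (median 0.27, camera adjusted p = 0.0248, adjusted p = 0.66 with an estimated correlation). The call was lost without control replicate 1 (camera adjusted p = 0.101) or reprogrammed replicate 1 (0.0596) and at 5 FPKM or more (0.0641). The JNK list median was 0.06 without control replicate 1, 0.47 without control replicate 2, 0.02 on a common sum, 0.41 after quantile normalization and 0.81 with the length trend removed. Its higher and lower genes numbered 6 and 4 without control replicate 1, and 8 and 4 without control replicate 2. Without reprogrammed replicate 1 or 2, wnd (adjusted p = 0.402 and 0.184) and Pvf2 (0.530 and 0.232) lost their calls. Of 11 JAK/STAT genes et and chinmo fell, or 5 lower and 1 higher adjusted over the list alone (median −1.0, camera adjusted p = 0.34, 0.84 with an estimated correlation). The et call was lost without control replicate 2 (0.0538) and without reprogrammed replicate 1 (0.398) or 2 (0.0778), and 5 JAK/STAT genes were lower without control replicate 1. Chromatin genes fell as a set, 8 of 32, or 18 adjusted over the list alone (median −1.14, camera adjusted p = 7.98e-06, adjusted p = 0.66 with an estimated correlation), among them the remodeler Iswi (−2.01 ± 0.30) and the Polycomb gene ph-p. With the length trend removed the chromatin median was −0.69 and 1 gene was lower, and after quantile normalization 2 were. Lower chromatin genes numbered 27 and 15 without control replicates 1 and 2, and in limma 0 and 1 without reprogrammed replicates 1 and 2 (4 and 9 at an unadjusted p under 0.05). Iswi and ph-p (0.240) lost their calls without reprogrammed replicate 1, and ph-p also without reprogrammed replicate 2 (0.141).

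Cell cycle genes gave few single calls. Of 46 mitosis genes, sti, a kinase of cytokinesis, fell (−1.64 ± 0.36, limma adjusted p = 0.0444). None passed adjusted over the list alone, and 18 were lower at an unadjusted p under 0.05. As a set they were lower (median −0.94, camera adjusted p = 0.000204, adjusted p = 0.66 with an estimated correlation). The mitosis median was −0.58 without control replicate 2, and 29 and 11 genes were lower without control replicates 1 and 2. Limma called 0 lower without reprogrammed replicate 1 or 2 (1 and 9 at an unadjusted p under 0.05), sti included (adjusted p = 0.434 and 0.204). The sti call was also lost after quantile normalization (0.0529) and with the length trend removed (0.135). None of 41 genes of the G1/S transition and DNA replication passed in limma, over all genes or adjusted over the list alone, with 7 lower at an unadjusted p under 0.05 (median −0.49, camera adjusted p = 0.0527, 0.84 with an estimated correlation). That list passed without control replicate 1 (median −0.82, camera adjusted p = 0.00468), with the length trend removed (0.0129), with no filter (0.0228), at 5 FPKM or more (0.0454) and on a common sum (0.0396). Its median was −0.16 without control replicate 2 (camera adjusted p = 0.419) and −0.35 without reprogrammed replicate 1 (0.296). Lower G1/S genes numbered 20 without control replicate 1 and 3 without control replicate 2. The ribonucleotide reductase gene RnrS stood at 126.6 ± 15.7 and 136.5 ± 24.3 FPKM, and the S-phase transcription factor gene E2f1 at 113.6 ± 26.0 and 56.5 ± 2.67.

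None of 37 ribosome biogenesis genes passed by either count, with 1 higher and 4 lower at an unadjusted p under 0.05 (median −0.38, camera adjusted p = 0.510, 0.90 with an estimated correlation). Without control replicate 1, 1 was higher and 19 lower with a median of −0.85, and without control replicate 2 the median was −0.07. None of 87 cytoplasmic ribosomal protein genes passed by either count, with 1 higher at an unadjusted p under 0.05 (median 0.02, mean −0.01 and camera pointing up; camera adjusted p = 0.112, 0.82 with an estimated correlation), and the median was −0.25 on a common sum and −0.26 after quantile normalization. Without control replicate 2 the ribosomal protein list passed as higher (median 0.23, camera adjusted p = 0.00842), and without control replicate 1, 12 of its genes were higher and 26 lower (median −0.26). Their share of all FPKM was 34.2% and 28.7% in the controls and 28.1% and 30.1% in the reprogrammed libraries. Of 23 apoptosis and DNA damage genes the p53 regulator Corp rose (1.79 ± 0.40) and the cell death gene skl fell (−1.64 ± 0.31), with 1 lower adjusted over the list alone (median −0.38, camera adjusted p = 0.613, 0.90 with an estimated correlation). Lower apoptosis genes numbered 11 without control replicate 1 (median −0.84) and 3 without control replicate 2 (median −0.04). Corp and skl lost their calls without reprogrammed replicate 1 (adjusted p = 0.350 and 0.365) or 2 (0.154 and 0.112), Corp also on a common sum (0.0688) and with the length trend removed (0.0687), and skl also on a common median (0.0524) and after quantile normalization (0.0566).

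Glycolysis genes rose as a set, with Gapdh2 from 705 ± 209 to 2286 ± 136 FPKM (1.73 ± 0.38, limma adjusted p = 0.0444) and Pgk from 187.0 ± 10.3 to 463 ± 36.4 (1.30 ± 0.27, limma adjusted p = 0.0409). The other 17 of 19 did not pass, and 4 were higher adjusted over the list alone (median 1.12, camera adjusted p = 0.000303, adjusted p = 0.66 with an estimated correlation). Eno, the enolase gene, stood at 410 ± 139 and 1078 ± 144 FPKM. The same list was 1.23 higher in control replicate 2 than in control replicate 1, and its median was 0.31 without control replicate 1 and 1.78 without control replicate 2. Gapdh2 and Pgk both lost their calls on a common sum (adjusted p = 0.0581 and 0.0529), after quantile normalization (0.0522 and 0.0745) and with the length trend removed (0.0619 and 0.0616), and also without reprogrammed replicate 1 (0.400 and 0.381) or 2 (0.240 and 0.332). Glycolysis genes called higher numbered 5 without control replicate 1, with 4 lower, and 13 without control replicate 2. None of 36 mitochondrial respiration genes passed by either count in limma, 5 being higher at an unadjusted p under 0.05, while the set was higher (median 0.48, camera adjusted p = 5.79e-05, adjusted p = 0.66 with an estimated correlation). It lost that call after quantile normalization (camera adjusted p = 0.0669). Mitochondrial genes called higher numbered 8 without control replicate 1, with 2 lower, and 10 without control replicate 2. The mitochondrial median was 0.11 without control replicate 1, 0.31 without reprogrammed replicate 2 and 0.15 with the length trend removed, and the list was 0.70 higher in control replicate 2 than in control replicate 1. COX5A, a cytochrome c oxidase subunit, stood at 1319 ± 503 and 1973 ± 225 FPKM. Of 24 lipid-handling genes Npc2a, a sterol carrier, rose from 107.8 ± 12.6 to 528 ± 16.8 FPKM (2.29 ± 0.27, limma adjusted p = 0.0297) and Lip4 rose as well, with 1 higher adjusted over the list alone (median 0.36, camera adjusted p = 0.00440, adjusted p = 0.66 with an estimated correlation). The lipid call was lost without control replicate 1 (median 0.06, camera adjusted p = 0.141; 4 genes higher and 5 lower), while without control replicate 2 the median was 0.80 with 10 genes higher. On a common sum it was 0.12, and with the length trend removed 0.80.

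Stress genes rose as a set of 29, with GstD2, GstD5 (4.67 ± 0.43), GstE1 (2.35 ± 0.54) and the heat-shock gene Hsp70Bb higher and the small heat-shock gene Hsp67Bc, chosen after its value was seen, lower (−2.34 ± 0.27). When adjusted over the list alone, 5 were higher and 1 lower (median 0.63, camera adjusted p = 0.000764, adjusted p = 0.61 with an estimated correlation). Without control replicate 1 the stress list median was 0.24 (camera adjusted p = 0.00468), with 10 genes higher and 6 lower, and without control replicate 2, 9 were higher and 1 lower. GstE1 lost its call with a pseudocount of 0.1 (adjusted p = 0.0542), on a common sum (0.0640), after quantile normalization (0.0527), with the length trend removed (0.0894) and without reprogrammed replicate 1 (0.107). Hsp70Bb stood at 49.1 ± 30.9 and 359 ± 11.3 FPKM, and its near-identical copies can share its reads. Hsp23 had 3404 ± 1815 and 7506 ± 1569 FPKM without a call. Of 21 immunity genes the peptidoglycan receptor gene PGRP-SA rose (2.70 ± 0.59) and the receptor gene Tl fell (−1.69 ± 0.28), which were also the calls adjusted over the list alone, 1 higher and 1 lower (median 0.08, or −0.16 on a common sum; camera adjusted p = 0.340, 0.66 with an estimated correlation). PGRP-SA lost its call without control replicate 2 (adjusted p = 0.0659) or reprogrammed replicate 1 (0.191), after quantile normalization (0.0681) and with the length trend removed (0.0619). Tl lost its call with the length trend removed (0.0609) and without reprogrammed replicate 1 (0.290) or 2 (0.133). Immunity genes numbered 3 higher and 3 lower without control replicate 1.

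Fat body and muscle markers differed between the 2 libraries of each group. Of 12 fat body markers the iron carrier Tsf1 rose from 44.5 ± 33.5 to 736 ± 201 FPKM (4.22 ± 0.58, limma adjusted p = 0.0324) and Fbp1 fell, with 2 higher and 1 lower adjusted over the list alone. Its median was −0.69 while camera pointed up (camera adjusted p = 0.340, 0.84 with an estimated correlation). Without reprogrammed replicate 1 that median was 0.96 (camera adjusted p = 0.000192), and without reprogrammed replicate 2 it was −3.42 (0.000330). Of 20 muscle markers Zasp52 fell (−1.53 ± 0.35), none adjusted over the list alone (median −1.14, camera adjusted p = 0.0607, 0.84 with an estimated correlation), and Act57B stood at 129.8 ± 130.0 and 35.9 ± 32.0 FPKM. The muscle list passed as lower without control replicate 1 (median −1.77, camera adjusted p = 0.0334) or reprogrammed replicate 2 (−1.75, 2.45e-05), and also on a common median (0.0241), with no filter (0.0387), with the replicate number as a block (0.00288) and after quantile normalization (0.0376). Its median was −0.36 without control replicate 2 and −0.65 without reprogrammed replicate 1, and 9 muscle genes were lower without control replicate 1. Zasp52 lost its call without reprogrammed replicate 1 (adjusted p = 0.495) or 2 (0.182). Both lists were higher in the second library of each group. The median difference between control replicates 2 and 1 was 1.67 for fat body and 1.57 for muscle markers, and between reprogrammed replicates 2 and 1 it was 2.69 and 1.20. The larval serum protein gene Lsp1beta, chosen after its values were seen, read 14.3 and 801 FPKM in the controls and 1.15 and 45.9 in the reprogrammed libraries.

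Of 21 blood cell markers the ferritin gene Fer1HCH rose (1.83 ± 0.33) while srp (−1.89 ± 0.32), ush and gcm fell, also 1 higher and 3 lower adjusted over the list alone (median −0.49, camera adjusted p = 0.440, 0.87 with an estimated correlation). Lower blood cell genes numbered 8 without control replicate 1 and 5 without control replicate 2. Fer1HCH, srp and ush lost their calls without reprogrammed replicate 1 (adjusted p = 0.332, 0.316 and 0.357) or 2 (0.163, 0.139 and 0.216), and with the length trend removed srp (0.0543) and ush (0.142) lost theirs. Imaginal disc markers fell as a set, 6 of 24 over all genes and 19 adjusted over the list alone (median −1.26, camera adjusted p = 0.000107, adjusted p = 0.61 with an estimated correlation), with en at −2.03 ± 0.40 and dac, also an optic lobe gene, at −2.02 ± 0.37. Lower disc genes numbered 17 and 12 without control replicates 1 and 2, and in limma 0 and 3 without reprogrammed replicates 1 and 2 (5 and 11 at an unadjusted p under 0.05). Both en (0.253) and dac (0.237) lost their calls without reprogrammed replicate 1. Of 13 salivary and ring gland markers fkh (−2.30 ± 0.34) and Kr-h1 fell, 2 also adjusted over the list alone (median −0.99, camera adjusted p = 0.0438, adjusted p = 0.74 with an estimated correlation). That call was lost without control replicate 1 (median −0.30, camera adjusted p = 0.744), on a common median (0.0591) and with a pseudocount of 0.1 (0.0646). Without control replicate 2, 10 gland genes were lower (median −1.39). Without reprogrammed replicate 1 or 2, fkh (0.191 and 0.0517) and Kr-h1 (0.385 and 0.249) lost their calls. Of 16 tracheal and cuticle markers obst-A (−2.11 ± 0.31), trh and Gasp fell, or 7 lower and 1 higher adjusted over the list alone (median −0.93, camera adjusted p = 0.0636, 0.66 with an estimated correlation). That list passed without control replicate 2 (0.0490) or reprogrammed replicate 2 (median −1.42, camera adjusted p = 0.00492), and also on a common median (0.0351), with the replicate number as a block (0.0290) and after quantile normalization (0.0435). Its lower genes numbered 8 without control replicate 1. Without reprogrammed replicate 1, obst-A (0.0826), trh (0.369) and Gasp (0.416) lost their calls, and without reprogrammed replicate 2, trh (0.121) and Gasp (0.133). None of 10 gut markers passed by either count or at an unadjusted p under 0.05 in limma (median −0.22 with camera pointing up, adjusted p = 0.660, 0.91 with an estimated correlation). The median difference of the gut list between control replicates 2 and 1 was −1.91 and between reprogrammed replicates 2 and 1 it was −3.86, and its median was −2.03 without reprogrammed replicate 1 (camera adjusted p = 3.1e-07) and 1.93 without reprogrammed replicate 2 (2.06e-06).

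None of 9 general control genes passed by either count, with 1 higher at an unadjusted p under 0.05 (median 0.07, camera adjusted p = 0.429, 0.87 with an estimated correlation), and their median was −0.21 on a common sum and −0.19 after quantile normalization. Without control replicate 1, 1 was higher and 3 lower.

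**Figure D3:**
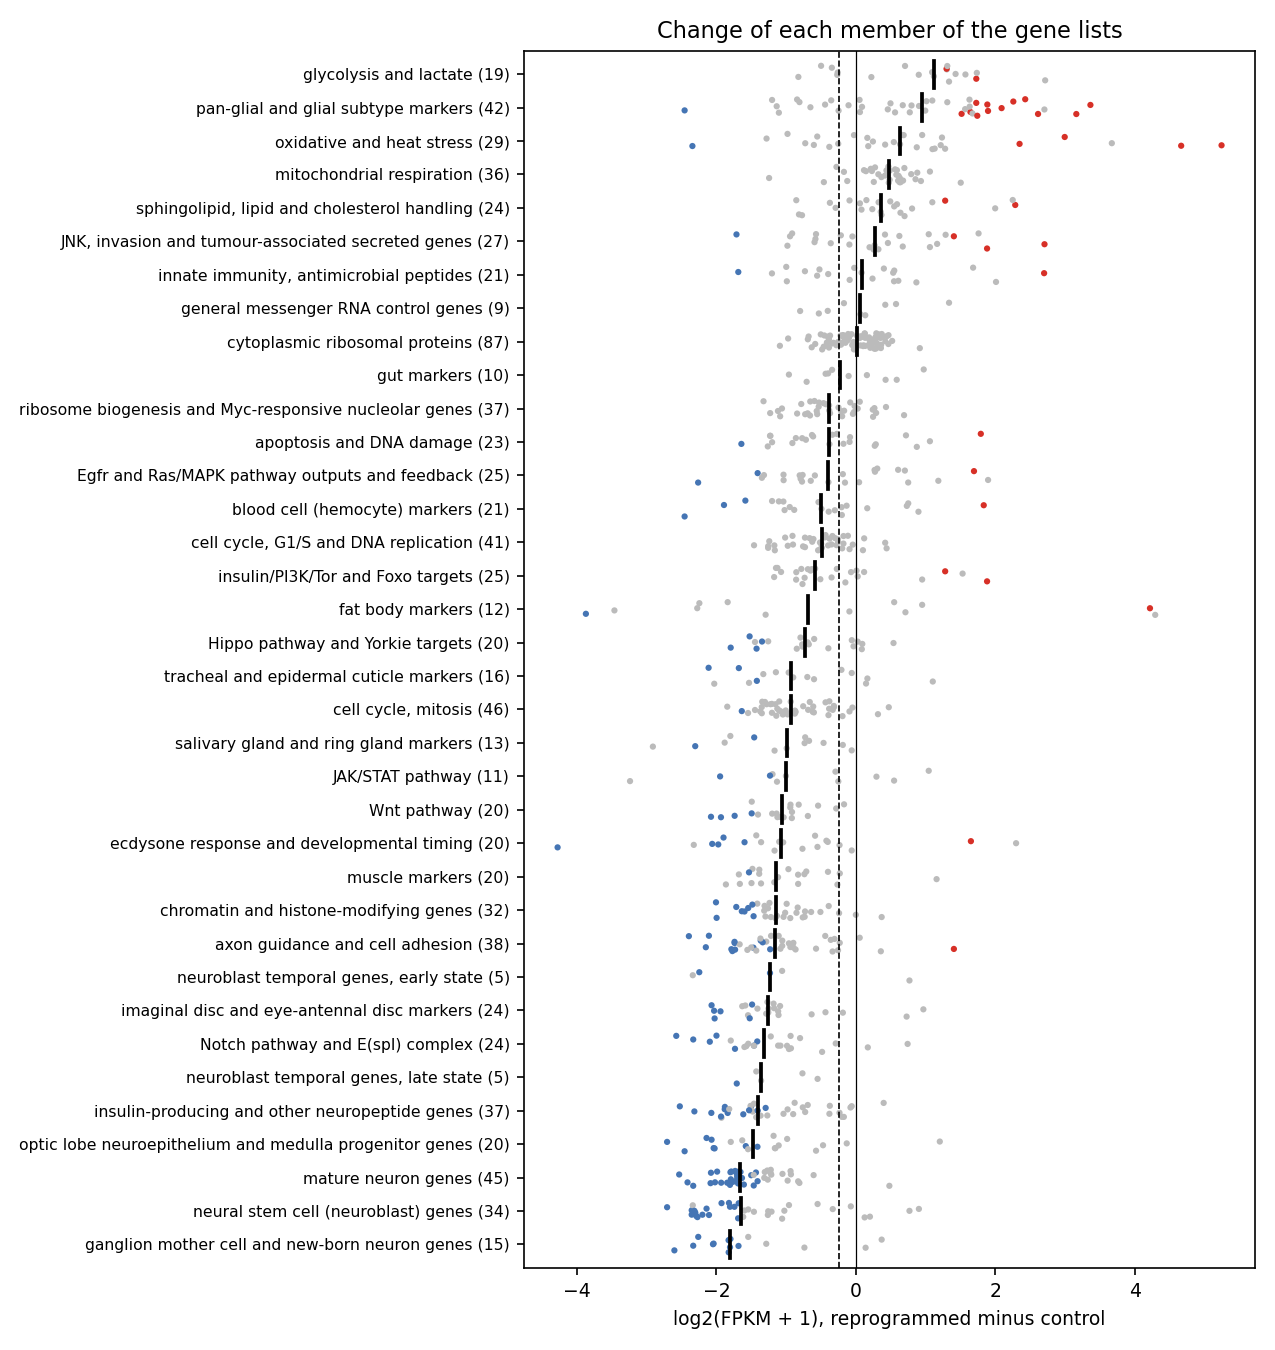
Log2 change, reprogrammed minus control, of each measured member of the 36 gene lists (points), with list medians as black bars, genes called higher in red, genes called lower in blue, other genes in grey, and the dashed line at the median of all genes, −0.25. The number of measured genes stands in parentheses. Glycolysis and glial genes lie highest, with medians of 1.12 and 0.95, and ganglion mother cell and newborn neuron genes lowest, at −1.80.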

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

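The common-sum, quantile, length-trend and identical-value settings were chosen after seeing the data; the others were set before. Of 118 named genes with a call, none changed sign in any setting. Picked for large changes, they were unlikely to, so this says little about stability. The call was kept by 111 of the 111 tested at 5 FPKM or more, 111 with a pseudocount of 0.1, 109 on a common sum and 105 on a common median. It was kept by 79 with the length trend removed and 78 after quantile normalization. Between 46 and 118 kept it with 1 library left out. Without any filter limma called 0 genes higher and 0 lower (3629 at an unadjusted p under 0.05), with a smallest adjusted p of 0.084. This setting tests 13997 genes and its prior degrees of freedom fall from 3.72 to 2.21. Egfr (2.33), Pi3K92E (4.38) and repo (1.64) lost their calls there. repo also lost it at a pseudocount of 0.1 (1.70) and on a common sum (1.39). Lower genes numbered 249 after quantile normalization and 329 with the length trend removed, against 801; the cause was not tested. With the replicate block 872 genes were higher and 1907 lower, which leaves 1 residual degree of freedom and an infinite prior, so the calls kept there say nothing about stability. Over all genes, the deviations of same-numbered libraries had a correlation of −0.035. That value cannot exclude a shared batch, since fat body and muscle markers were higher in the second library of each group. Gut markers were lower there, by −1.91 in control and −3.86 in reprogrammed libraries. The block ended the calls of the Hippo and late temporal lists and gave calls to the muscle and tracheal lists. Leaving out 1 library gave 181 to 1265 higher and 75 to 3313 lower genes, and 2.15 to 2.52 for Egfr, 3.90 to 4.86 for Pi3K92E and 1.20 to 2.08 for repo. List medians then ranged from 0.85 to 1.11 for glial, −1.84 to −1.45 for neural stem cell, −1.96 to −1.59 for ganglion mother cell and −1.83 to −1.38 for mature neuron genes. Of 36 lists 21 passed, between 18 and 23 in the other settings, and 0 with an estimated correlation, where the medians are the same (0.95, −1.65, −1.80 and −1.65) and the smallest adjusted p was 0.61. Counting genes with identical values once left 383 higher and 800 lower genes, and all 405 and 801 changed by at least 1 on the log2 scale. Signs of values without a call turned as follows, the cause not tested. On a common sum: immunity list −0.16, general control genes −0.21, ribosomal proteins −0.25, RnrS −0.17 and rl −0.22. After quantile normalization: general control genes −0.19, ribosomal proteins −0.26 (camera adjusted p = 0.038), RnrS −0.07, spi −0.08 and rl −0.24. With the length trend removed: immunity −0.30, general control genes −0.03, ribosomal proteins −0.34, RnrS −0.11, Inx2 0.32 and Akt 0.17. Leaving out 1 library turned immunity (−0.06 to 0.21), fat body (−3.42 to 0.96), gut (−2.03 to 1.93), general control genes (−0.09 to 0.30), ribosomal proteins (−0.26 to 0.23), RnrS (−0.08 to 0.28) and rl (−0.44 to 0.53). The planned count-based tests were not run, since the files hold FPKM. Depth limits low genes, since 1 FPKM over 1 kilobase stands for 11.2 to 12.2 reads.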

Other observations

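The tests of gene families, of the length trend, of quantile normalization, of the spread of glial genes and of the heat-shock genes were chosen after the data were seen, as were the genes named here and in the next paragraph, while those of a smaller neuronal or stem cell share and of the summed Hsp70 copies were written down before their values were computed. Among detoxification families, glutathione S-transferases and cytochrome P450s were enriched among the higher genes. UDP-glycosyltransferases were not, with 1 of 13 higher (Fisher's exact test, two-sided, adjusted p = 0.77). Of 28 tested glutathione S-transferase genes 12 were higher, against 4.1% of all tested genes (Fisher's exact test, two-sided, adjusted p = 4e-09 over 24 comparisons of 12 families), and GstZ2 and GstO3 were lower. The calls of GstO3, Cyp4s3 and Cyp4e2 were lost without reprogrammed replicate 1 (limma adjusted p = 0.451, 0.359 and 0.367) or 2 (0.221, 0.0801 and 0.158). GstD9 rose from 12.7 ± 1.75 to 120.3 ± 7.99 FPKM (SD, n = 2; log2 change 3.16 ± 0.27, limma adjusted p = 0.0206), and GstE7 and GstE6 rose by 3.78 and 3.77. Of 40 cytochrome P450 genes 10 were higher and Cyp4s3 and Cyp4e2 lower (adjusted p = 2.8e-05 for the higher ones by Fisher's exact test). Cyp9h1 rose by 3.51 ± 0.29, Cyp6a17 by 3.45 ± 0.42 and Cyp4g15, a glial marker, by 2.26 ± 0.38. The median change stayed above 0 in each scaling, from 0.73 to 1.31 for the transferases and from 0.29 to 0.92 for the P450s. Of 10 nicotinic acetylcholine receptor subunit genes 5 were lower, against 8.1% of all tested genes: nAChRalpha1, nAChRalpha2, nAChRalpha4, nAChRalpha6 and nAChRbeta1 (Fisher's exact test, adjusted p = 0.0038, family median −1.58, and −0.90 with the length trend removed). This test took no account of length, and in the eighth of genes with the longest transcripts 23.9% were lower. Both nAChRalpha1 and nAChRalpha6 also stand in the mature neuron list, so this result is not separate from that list. The nAChRalpha6 and nAChRalpha1 calls were lost on a common median (limma adjusted p = 0.0704 and 0.0528), after quantile normalization (0.128 and 0.0821) and with the length trend removed (0.128 and 0.151). The nAChRalpha2 call was lost after quantile normalization (0.0549) and that of nAChRalpha4 with the length trend removed (0.097). The calls of all 5 were lost without reprogrammed replicate 1 (limma adjusted p from 0.299 for nAChRbeta1 to 0.412 for nAChRalpha1) or reprogrammed replicate 2 (from 0.0969 for nAChRalpha2 to 0.183 for nAChRalpha4). No call was made among 35 proteasome subunit or 73 mitochondrial ribosomal protein genes. Genes within a family are not independent, so these p-values describe these libraries.

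Arc1, which encodes a capsid-forming protein of synapses, rose from 30.8 ± 1.16 to 760 ± 126 FPKM (4.57 ± 0.27, limma adjusted p = 0.0143), and its neighbour Arc2 by 3.62 ± 0.35. The Hox gene Scr read 34.2 and 25.8 FPKM in the controls and 2.94 and 4.58 in the reprogrammed libraries (−2.71 ± 0.35, limma adjusted p = 0.0308), while the median change of the 7 tested Hox genes was −0.78 (−0.08 with the length trend removed). The noncoding RNA lncRNA:roX1 of dosage compensation changed from 442 ± 20.7 to 107.2 ± 38.2 FPKM (−2.08 ± 0.34, limma adjusted p = 0.0340). That call was lost with the length trend removed (adjusted p = 0.0518). A second such RNA, lncRNA:roX2, read 104.74 and 101.66 FPKM in the controls and 25.51 and 56.15 in the reprogrammed libraries. It had no call (−1.42 ± 0.41, limma adjusted p = 0.0724). Sex of the pooled larvae is not among the sample labels used here, and a difference in sex between the groups was not tested and is not excluded. Of 58 replication-dependent histone gene copies 26 were higher, which make 6 of 11 distinct sets of values because copies share reads. Messenger RNA was selected with oligo(dT) beads, so these values may not stand for total histone transcripts.

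Mature neuron and neural stem cell genes were lower in reprogrammed samples, each list with a median of −1.65. A trend on transcript length could lower both, but with it removed mature neuron genes still lay 0.61 below all genes (difference −0.61), and none of 10000 length-matched random lists lay as low as either list, so length alone does not account for it. One factor per library moves all genes alike and decides nothing here. Quantile normalization can move a list against all genes, but after it both medians still lay at least 1.25 below that of all genes. The smaller of both differences was −1.25. A smaller share of neuronal RNA alone would move all neuronal genes by 1 factor. The spread of the 45 changes did not exclude that (heterogeneity Q of 105.3, with 120.6 as the point that 2.5% of 10000 simulations of equal changes exceeded). With 2 libraries per group this test is weak, and it was not repeated with the length trend removed. Random lists matched to the mature neuron genes on length had a median change of −0.87, so part of the −1.65 was shared by other genes of like length. For the 34 neural stem cell genes the spread was wider than that of 1 common factor (Q of 287.2 against 97.3). This argues against a smaller stem cell share alone for the list as a whole. The limit set for this test took all 34 as specific to stem cells. Of these, 13 stand in another list, which does not show that other cells express them, and Q without them was not computed. Whether a smaller share contributed next to lower levels per cell cannot be told from these values.

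Glial genes did not move alike, with Q of 607.6 over 42 markers against 113.1 for simulated equal changes, moody at 3.36 and gcm at −2.46. A larger glial share alone would raise genes specific to glia by 1 factor, so this spread argues against it for the 42 markers as a whole. Of the markers, 6, gcm among them, also stand in other lists and could follow other cells, and Q without them was not computed. Whether a larger share contributed next to a change of glial state cannot be told from these values. The length trend does not account for the spread, since Q was 618.3 with it removed, against 117.4. No separate test of a change of glial state was made.

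Hsp70Bb (from 49.1 ± 30.9 to 359 ± 11.3 FPKM) and the eye colour gene w (2.97 ± 0.28, from 78.0 ± 10.5 to 617 ± 69.9 FPKM, limma adjusted p = 0.0222) both rose. A general heat-shock response would raise the other 11 heat-shock genes too, but their median change was 0.18 (SD 1.08), none was called higher and 1 was lower, Hsp67Bc, chosen after its value was seen. A shift of reads between near-identical copies is argued against by the sum of 4 Hsp70 copies, 58.9 and 126 FPKM in control and 431 and 485 in reprogrammed libraries (log2 ratio 2.31). Fly transgene vectors commonly carry w and parts of Hsp70 genes, so reads from additional vectors may be the source, but the rise of w (2.97) cannot be told apart from expression of the chromosomal genes because the files give no value per position. A biological rise of both genes was not tested.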
